A study of Danio rerio with 4 samples.

How the data were processed

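RNA was measured in whole eyes of zebrafish (Danio rerio) aged 3.5 months after fertilisation, with fish of both sexes in each sample per the labels. There were 4 Affymetrix arrays, 1 for each of 4 genotypes: wildtype, eys-/- homozygotes, lrp5-/- homozygotes and fish heterozygous at both loci (eys+/-; lrp5+/-, called double heterozygotes here). Per the labels' protocols, total RNA was extracted with TRI Reagent and hybridised as biotin-labelled single-stranded cDNA. The sources used here do not say how many fish gave RNA to an array, or at what time of day the eyes were taken.

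The deposited values are log2 signals of 75212 probe sets on the 4 arrays. RMA and Transcriptome Analysis Console 4.0 are named in the submitters' processing notes. RMA by its definition corrects the background, makes the distributions of the arrays equal by quantile normalization and summarises probes by median polish, so a shift of most genes in one direction would be removed. The log2 scale was read from the values: the deposited columns for wildtype, eys-/-, lrp5-/- and the double heterozygote have medians of 5.04, 5.06, 5.03 and 5.04 and were not centred by gene. Array annotation dated 2013 names 21661 of the probe sets, 20806 with 1 gene symbol and 855 with several. The other 53551 probe sets are unnamed here. Only probe sets with 1 symbol were used for genes, which gave 19260 genes, 1365 of them with more than 1 probe set. Of the named probe sets, 20323 had a gene identifier in the RefSeq gene table of assembly GRCz12tu, through which 1 symbol was updated. That table also gave the synonyms used to match gene lists and the order of genes along chromosomes. Coordinates are not printed, because the build of the array is not given in the sources used here.

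Each gene was represented by its probe set with the highest mean over the 4 arrays. A gene counted as measured in a comparison when the higher of the 2 arrays was at or above 6.57, the median of all named values. A measured gene was called higher or lower when the arrays differed by 2-fold or more, a log2 difference of 1. There are no replicates: with 1 array per genotype no spread between fish can be estimated, no p-value is given, and every difference compares 2 arrays. The number of arrays limits the precision. The robust SD of the log2 difference over measured genes ran from 0.17 to 0.23 over the 6 pairs of arrays. Genes of one array are not replicates of each other. Only the higher reading of a pair had to reach the measured level. Of the 255 named values, 8 rest on a lower reading below the median of its array, not shown to be above background. They are given as uncertain in size. The array median is no measure of background, so readings just above it are not shown to be above background either.

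The named genes follow a rule written before the data were examined. For each comparison with wildtype they are eys and lrp5, the 10 genes with the largest positive and the 10 with the largest negative difference, and up to 4 members with the largest absolute difference of each gene list that stood apart. Clone-style names were skipped, and their number among the top genes is given. For the comparisons with the homozygotes they are the 5 largest in each direction. Probe sets of several genes are never named. Genes named outside this rule are said to be so.

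A total of 36 gene lists for cell types and pathways of the eye was also fixed before the data were examined. For each, the median log2 difference of its measured members was set against 10000 random lists of the same size, drawn with replacement within 20 bins of mean level. A list stood apart when its median lay at or below the 2.5th or at or above the 97.5th percentile of those random lists. This describes the arrays and is no test of the genotypes, because genes of a list vary together. The share of each tissue in the whole eyes was not measured, so a list's shift cannot be told apart from a change in that share. Lists with fewer than 5 measured members were left out. Synonym matching gave 4 wrong matches, which were dropped after a first look at the list results. A further 5 lists were made after single genes had been seen: 2 of clock genes by phase, and lists of glucocorticoid targets, of other rod genes and of myelin genes.

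Comparisons with one wildtype array share its chance values. The correlation, covariance and shared calls of such comparisons were therefore set beside 100 simulated sets of unchanged arrays, with the noise taken from the pairs of arrays by level. Correlations of differences that share no array were also computed. Genes next to eys and lrp5 were compared with all other windows of 50 neighbouring measured genes.

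The rules were tested on simulated data. In a simulated array set against wildtype over 10412 genes, 0 of 50 genes changed by 1.5-fold were called, as were 46 of 50 at 2.5-fold, 50 of 50 at 3-fold and 50 of 50 at 4-fold. Of 10212 unchanged genes in it, 0 were called. Of 100 unshifted lists of 20 genes, 5 lay outside the central range, and all 100 lists shifted by 0.3 lay above it. The simulated noise did not make genes of a list vary together, so these counts are no error rates for the real arrays. A shift of 0.3 is larger than most list medians given below, so smaller shifts were not tried.

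Alternatives covered the level filter, renormalization, centring, removal of a trend with level by loess (span 0.3), the choice of probe set, the reference array, the fold threshold, the matching of random lists and the mean in place of the median. The mean of the other 3 arrays holds the other mutant arrays, so a shift shared with them becomes smaller or can turn sign by construction. Shared calls and correlations were also computed without the skeletal muscle, red blood cell, lens and surface epithelium lists. Counts without clock genes, and against the mean of the 2 homozygotes, were added after the data had been seen. A count was held to have moved when it differed by over 1.5 times, and a correlation when it differed by over 0.1, a tolerance set after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.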

Results

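Gene expression was compared between the eyes of wildtype zebrafish and those of eys-/-, lrp5-/- and doubly heterozygous eys+/-; lrp5+/- fish. The gene eys encodes a protein of the extracellular matrix around photoreceptors and is mutated in a form of retinitis pigmentosa. The gene lrp5 encodes a Wnt co-receptor through which Norrin acts on retinal vessels, and it is mutated in familial exudative vitreoretinopathy. The 4 arrays, 1 per genotype with no replicates, had median log2 signals between 5.03 and 5.06, and any pair of them correlated at 0.978 to 0.983 over all probe sets. Differences below are log2 values of single arrays.

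The mutated genes were looked at first. In the array annotation used here, 0 probe sets carry the name eys, so its level was not analysed here. The 1 probe set of lrp5 read 7.39 in wildtype, 7.27 in eys-/-, 7.17 in lrp5-/- and 6.92 in the double heterozygote. The lrp5 differences from wildtype of -0.12, -0.22 and -0.47 were all under 2-fold, and the lowest level was not in the homozygote. Where this probe set lies relative to the mutation is not known here, so it does not check the labels.

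The first question was how eyes of double heterozygotes differ from wildtype eyes. The highest was fkbp5, a chaperone of the glucocorticoid receptor and a classical glucocorticoid target, 7.85-fold above wildtype (2.97). It was followed by the transcription factor mef2ca at 2.93, the glucocorticoid-responsive transcription factor klf9 at 2.72 and the Rev-erb family repressor nr1d4b at 2.43. Higher too were smu1b at 2.34, gadd45ga of the growth arrest and DNA damage family at 2.27, the pteridine synthesis gene gch2 at 2.23, rtn2b at 2.02 and the cell cycle inhibitor cdkn1a, 4.01-fold above wildtype. The MHC class II gene mhc2daa was higher by 2.31, an uncertain value because related genes can share its probes. The lower readings of mhc2daa, cdkn1a and bmal1a lay below the median of their array, so the sizes of these differences are uncertain. Those of kcnk5a (5.05) and ttll6 (5.16), named below, lay just above that median, and their sizes are uncertain too. The lowest was ndrg1b, at 8.83 against 11.58 (-2.75). The clock activators bmal1a and bmal1b differed by -2.23 and -1.61, dhrs12la by -2.14, the tubulin ligase family gene ttll6 by -2.02, the potassium channel kcnk5a by -1.73 and the microRNA gene mir726 by -1.62. The heparan sulphate sulphotransferase hs3st3b1a was 3.99-fold lower. The cone genes guca1ab.1 at -1.96 and opn1mw1, a green opsin, at -1.90 have near-identical copies and are uncertain. Among these top genes 2 clone-style names were skipped on the higher side and 1 on the lower side. Altogether 128 genes were higher and 51 lower by 2-fold or more, and 10255 of 10434 measured genes were neither. Set against the mean of the other 3 arrays in place of wildtype, the counts were 83 and 21.

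Of the 34 gene lists with enough members, 7 stood apart as higher in the double heterozygote and 4 as lower. Immediate early genes, which respond within minutes to stimulation, had a median of 0.26 (100th percentile of random lists): of 32 measured, 4 were higher, 0 lower and the rest neither, with klf9, gadd45ga, npas4a at 1.51 and nr4a1 at 1.13 at the top. Cartilage, bone and fibrous matrix genes had a median of 0.29 (100th percentile), and 2 of 39 were higher, the corneal proteoglycan kera by 1.73 and biglycan bgna by 1.08, while the collagens col10a1a and col1a2 differed by 0.92 and 0.76. Surface epithelium genes had a median of 0.15 (99.97th percentile) with 0 of 40 higher and 1 lower. The lower one was the haem-binding family gene soul5 at -1.15, while epcam differed by -0.70 and the desmosome genes dspa and pkp3a by 0.66 and 0.64. Oxidative phosphorylation genes had a median of 0.14 (100th percentile) with none of 75 past 2-fold and values of 0.55 for ndufa7, 0.50 for cox7a2l, 0.50 for cox8a and 0.48 for atp5mc1. Melanin pigment cell genes had a median of 0.21 (99.3th percentile) with 0 of 14 past 2-fold, led by slc24a5 at 0.66, tyrp1b at 0.55, gpr143 at 0.52 and kita at 0.51. The 7 measured microglia and macrophage genes had a median of 0.28 (98.7th percentile) with 0 past 2-fold; coro1a, csf1ra and mpeg1.2 differed by 0.45, 0.40 and 0.36 and the protease ctsba by -0.74. Synaptic genes had a median of 0.10 (98.5th percentile), and 1 of 44 was higher, pcloa of the presynaptic active zone at 1.08, beside sv2ba at 0.95, slc17a7b at 0.80 and cacna2d4a at -0.90.

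On the lower side, endothelial genes had a median of -0.16 (0.14th percentile), and 1 of 29 was lower, mmrn2a at -1.37, beside she at -0.83, the VEGF receptor gene kdr at -0.57 and aplnrb at -0.56. Pericyte and smooth muscle genes had a median of -0.14 (1.17th percentile) with 0 of 17 past 2-fold: abcc9 differed by -0.57, foxf2b by -0.40, rgs5a by -0.39 and cnn1b by 0.65. Red blood cell genes had a median of -0.15 (1.54th percentile) with 0 of 15 past 2-fold, among them fech at -0.40, creg1 at -0.32, hebp2 at -0.30 and tfr1a at 0.35. Cytosolic ribosomal protein genes had a median of -0.14, below every random list, with 0 of 58 past 2-fold; rpl26, rpl5b, rps25 and rps18 differed by -0.47, -0.46, -0.44 and -0.40. The lists closest to the mutated genes did not stand apart: Norrin and Wnt signalling had a median of -0.03 over 32 genes, vitreoretinopathy genes -0.12 over 7, and dystroglycan and eys-related matrix genes -0.00 over 20 (44.9th percentile). Rod and cone phototransduction had medians of -0.09 and -0.03 and lay inside the range, and the mean of the rod list was of the other sign (0.068), as was that of Norrin and Wnt signalling (0.012). Against the mean of the other 3 arrays the surface epithelium median was -0.04 and that of red blood cells 0.08, both opposite in sign, and the melanin, endothelial, oxidative phosphorylation and synaptic medians lay inside the range. With the mean in place of the median, the melanin, microglia, red blood cell, pericyte, surface epithelium and synaptic lists lay inside it.

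**Figure D1:**
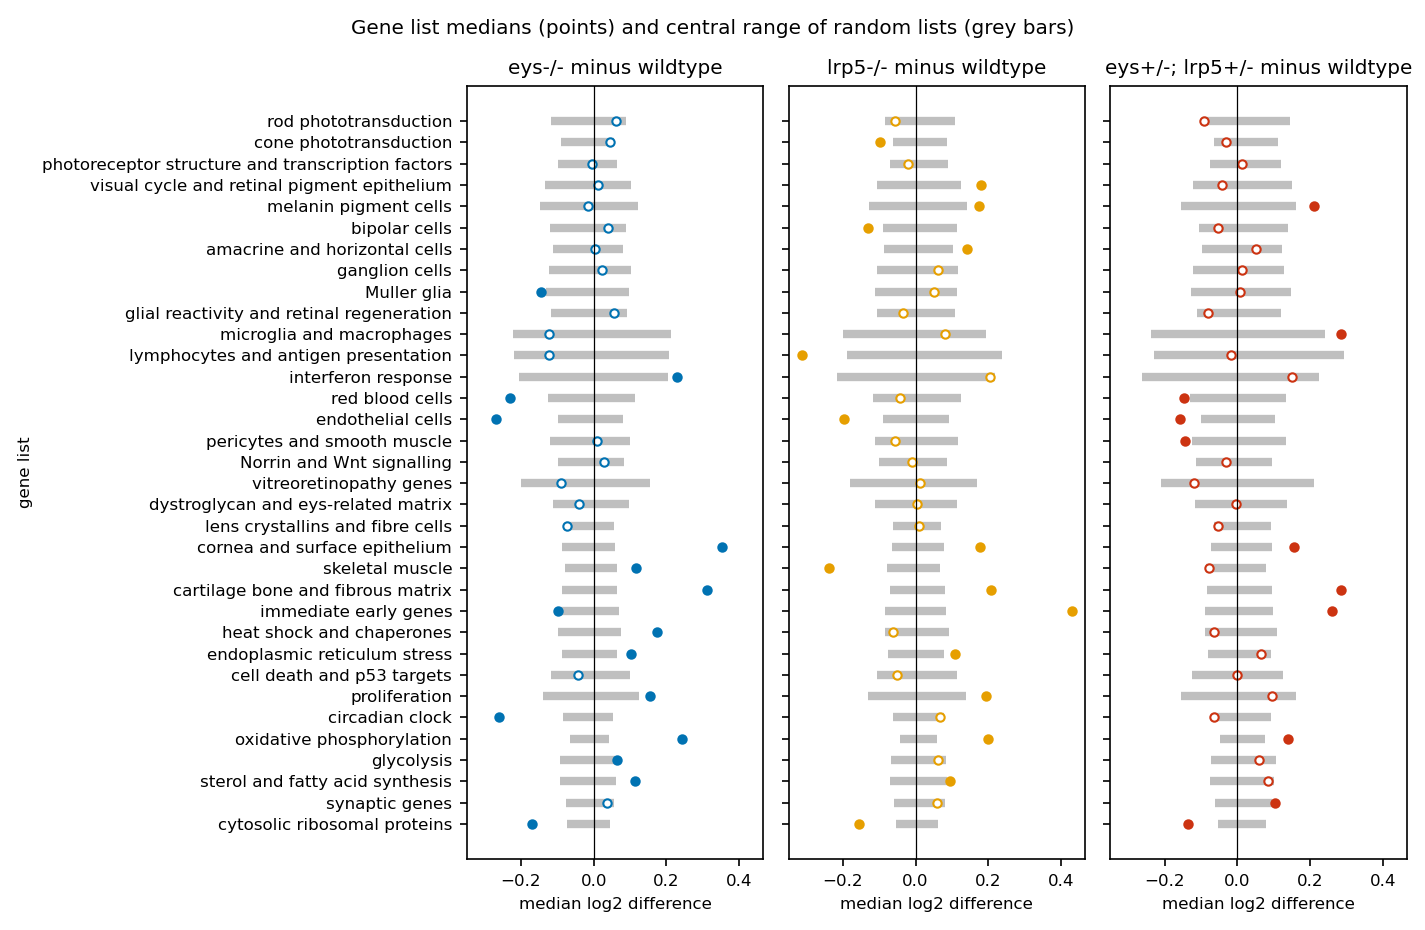
Each point is the median log2 difference from the wildtype array (horizontal axis) of 1 gene list (vertical axis) in 1 mutant array, filled where it lies outside the grey bar, the central 95% of 10000 random lists matched on level. The fibrous matrix median lies at 0.29, 0.31 and 0.21 in the double heterozygote, eys-/- and lrp5-/- arrays, and the endothelial median at -0.16, -0.27 and -0.20.

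Clock genes differed in both directions in the double heterozygote. Of 46 measured circadian clock genes, 9 were higher, 8 were lower and the other 29 neither, so that the median of -0.06 lay inside the range of random lists (2.59th percentile) and the mean was 0.015. Besides nr1d4b, bmal1a and bmal1b, and named after their values were seen, per1a and nr1d4a were each higher by 1.88, dbpb by 1.61, and rorcb and nfil3-5 were each lower by a difference of -1.50.

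**Figure D2:**
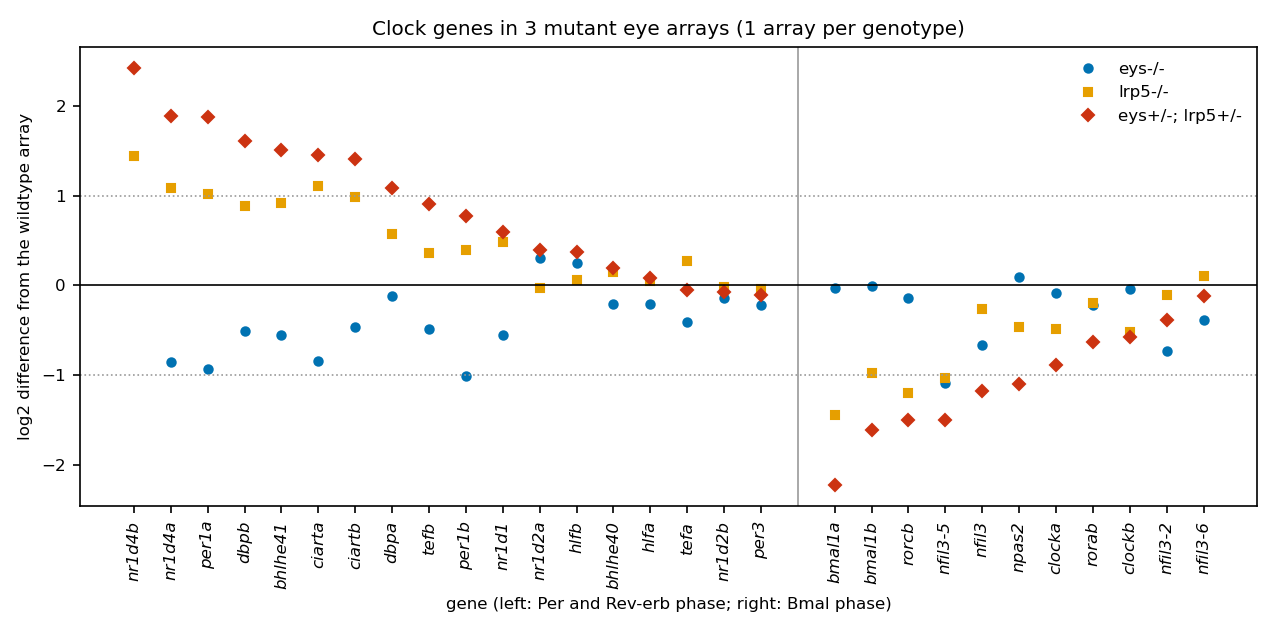
Log2 difference from the wildtype array (vertical axis) of each measured clock gene (horizontal axis), for genes that peak with Per and Rev-erb genes (left) and with Bmal genes (right); circles are eys-/-, squares lrp5-/- and diamonds eys+/-; lrp5+/-, with dotted lines at 2-fold. In the double heterozygote per1a lies at 1.88 and bmal1a at -2.23; in eys-/- they lie at -0.93 and -0.03.

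The second question was how eyes of eys-/- fish differ from wildtype eyes. Again fkbp5 was highest, 7.60-fold above wildtype (2.93). Also higher were pfkfb4b, whose product controls glycolytic flux, at 1.49, the glycogen-targeting subunit gene ppp1r3c2a at 1.31, bgna at 1.29 and col10a1a at 1.24. The secretory epithelial gene agr1 was higher by 1.44, the transcription factors klf2a and klf9 by 1.41 and 1.28, eva1bb by 1.29 and the calpain capn2l by 1.25. The lowest was paqr3b, at 4.85 against 8.30 (-3.44), a size that is uncertain because 4.85 lies below the median of the eys-/- array. Also lower were dhrs12la at -1.95, the vitamin B12 binding protein gene tcnbb at -1.68, the arrestin family gene arrdc3b at -1.60, the myelin basic protein gene mbpa at -1.59, the prostaglandin synthase ptgs2b at -1.42, the collagen hydroxylase p4ha1b at -1.34 and the histone variant macroh2a2 at -1.31. The tubulin tubb4bl at -1.87 and the lens crystallin crygm2e at -1.33 belong to families with near-identical members and are uncertain. Clone-style names were skipped 7 times on the higher and 3 times on the lower side. In all, 34 genes were higher and 32 lower, and 10369 of 10435 were neither. With no filter on level 161 genes passed and with a stricter one 39, and against the mean of the other 3 arrays 34 were higher and 62 lower.

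In eys-/-, 10 lists stood apart as higher and 6 as lower. Surface epithelium genes had a median of 0.35 (100th percentile), and 1 of 41 was higher, agr1, with icn at 0.85, krt1-19d at 0.81 and anxa1b at 0.74. Fibrous matrix genes had a median of 0.31 (100th percentile), and 2 of 38 were higher, bgna and col10a1a, with the crosslinking enzyme loxl2b at 0.97 and col1a2 at 0.91. Oxidative phosphorylation genes had a median of 0.24 (100th percentile) with none of 74 past 2-fold; ndufb10 differed by 0.75, ndufab1a and ndufs1 by 0.63 each and cycsb by 0.55. Heat shock and chaperone genes had a median of 0.17 (99.99th percentile): 1 of 30, fkbp5, was higher, while hsp90aa1.1, the collagen chaperone serpinh1b and hsp90aa1.2 differed by 0.83, 0.68 and 0.51. Of 35 sterol and fatty acid synthesis genes (median 0.11, 99.9th percentile) 2 were higher, the squalene epoxidase gene sqlea at 1.07 and fabp4b at 1.04, beside hmgcs1 at 0.80 and fabp1a at 0.76. The other 5 higher lists were endoplasmic reticulum stress (median 0.10; calr3a at 0.55), proliferation (0.15; ccnd2a at 0.61), interferon response (0.23 over 6 genes; trim25 at 0.47), glycolysis (0.06; 1 of 35 higher, pfkfb4b) and skeletal muscle (0.12). Among 47 skeletal muscle genes 0 were higher and 1 lower, the myoglobin gene mb at -1.06, while pvalb3 and myl1 differed by 0.84 and 0.63 and ckma by -0.60.

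The lower lists in eys-/- were endothelial genes, with a median of -0.27 and 0 of 29 past 2-fold (cldn5b and sox18 at -0.60, tie1 at -0.56, tal1 at -0.55), and red blood cell genes, with a median of -0.23 and 0 of 15 past 2-fold (rhag at -0.81, nt5c2l1 at -0.73, creg1 at -0.66). The marker tal1 is in both lists. Circadian clock genes had a median of -0.26, below every random list, and 2 of 44 were lower, nfil3-5 at -1.09 and per1b at -1.01, with per1a at -0.93 and nr1d4a at -0.85; per1b was under 2-fold after renormalization, centring or trend removal. Ribosomal protein genes had a median of -0.17 with 0 of 58 past 2-fold (rpl26 at -0.50, rps25 at -0.48, rpl30 and rps18 at -0.46 each). The 17 Muller glia genes had a median of -0.15 (1.40th percentile) with 0 past 2-fold: the filament gene vim differed by -0.63 and the potassium channel kcnj10a by -0.52, while glulb and fabp7a differed by 0.51 and 0.49. Immediate early genes had a median of -0.10 (1.98th percentile), although 2 of 30, klf2a and klf9, were higher and jun differed by 0.65; ppp1r15a differed by -0.73. Rod and cone phototransduction had medians of 0.06 and 0.05 (92.5th and 94.5th percentiles) and did not stand apart, nor did dystroglycan and eys-related matrix genes at -0.04. With the mean in place of the median, the Muller glia, skeletal muscle, immediate early and glycolysis lists lay inside the range. Against the mean of the other 3 arrays 13 lists stood apart in place of 16.

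The third question was how eyes of lrp5-/- fish differ from wildtype eyes. The highest was gadd45ga at 2.48 (5.58-fold), followed by gch2 at 1.98. The Fos genes fosab and fosb were higher by 1.96 and 1.77 and the neuronal activity gene npas4a by 1.58. Other genes on the higher side were mef2ca at 1.80, znfl1g at 1.70, ppp1r3c2a at 1.49, nr1d4b at 1.45 and frmd5b at 1.34. The lowest were tcnbb at -1.87, kcnk5a at -1.68, ndrg1b at -1.63, apold1a, a gene of endothelial cells, at -1.57, the protocadherin pcdh2g28 at -1.57, dhrs12la at -1.55, bmal1a at -1.44, hs3st3b1a at -1.30 and the smoothelin gene smtnb at -1.22; tubb4bl at -1.64 is uncertain. The lrp5-/- readings of tcnbb, kcnk5a and pcdh2g28 and the wildtype reading of znfl1g lay just above the median of their array. The sizes of these differences are therefore uncertain too. Clone-style names were skipped 8 times on the higher and 3 times on the lower side. In all 41 genes were higher and 29 lower, and 10356 of 10426 were neither. Without a filter on level 126 genes passed, and against the mean of the other 3 arrays 33 did.

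In lrp5-/-, 10 lists stood apart as higher and 6 as lower. Immediate early genes had the highest median of the fixed lists in this comparison, 0.43 (100th percentile), and 4 of 35 were higher: gadd45ga, fosab, fosb and npas4a. Fibrous matrix genes had a median of 0.21 with 0 of 37 past 2-fold (col10a1a at 0.98, matn1 at 0.87, bgna at 0.79, kera at 0.68). Surface epithelium genes had a median of 0.18 with 0 of 40 past 2-fold (agr1 and evpla at 0.98 each, anxa1b at 0.89, krt1-19e at -0.96). Oxidative phosphorylation genes had a median of 0.20 with 0 of 74 past 2-fold (cycsb at 0.62, ndufa6 at 0.53). Visual cycle and pigment epithelium genes had a median of 0.18 (99.7th percentile) with 0 of 17 past 2-fold; the isomerase gene rpe65a differed by 0.60 and rdh8b by 0.48, but dhrs9 by -0.38 and rbp3 by -0.34. Melanin pigment cell genes had a median of 0.17 over 12 genes (tyrp1b at 0.50, dct at 0.38, tyr at 0.36). The other 4 higher lists were amacrine and horizontal cells (median 0.14; onecutl at 0.37, lhx1a at -0.38), endoplasmic reticulum stress (0.11; the stress sensor ern1 at 0.87), proliferation (0.19; pcna at 0.39) and sterol and fatty acid synthesis (0.09; fabp4b at 0.66, hmgcra at 0.62), with 0 past 2-fold in each.

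The lower lists in lrp5-/- included endothelial genes, with a median of -0.20, where 1 of 29 was lower, mmrn2a at -1.05, beside kdr at -0.45 and aplnrb at -0.42. Skeletal muscle genes had a median of -0.24, and 1 of 44 was lower, mb at -1.16, beside tnnc2.2 at -0.79, ckma at -0.70 and acta1b at -0.67. Ribosomal protein genes had a median of -0.16 with 0 of 58 past 2-fold (rpl14 at -0.46, rpl23a at -0.45). The 5 lymphocyte and antigen presentation genes had a median of -0.31 (0.18th percentile), with b2m at -0.51, b2ml at -0.41 and cd74a at -0.31. Cone phototransduction genes had a median of -0.10 (0.06th percentile): of 36, 1 was lower, guca1ab.1 at -1.20, and 1 higher, guca1g at 1.11, beside guca1d at 0.93 and the green opsin opn1mw4 at -0.87, all of families with near-identical copies and so uncertain. Bipolar cell genes had a median of -0.13 (0.29th percentile) but a mean of 0.0010; samsn1b differed by 0.93 and samsn1a by -0.74, beside cabp2a at 0.50 and gnao1a at 0.40. Of 46 circadian clock genes 4 were higher and 3 lower, and the median of 0.07 lay inside the range. Norrin and Wnt signalling genes had a median of -0.01 over 31 genes, and 0 were past 2-fold. Against the mean of the other 3 arrays the fibrous matrix median was -0.0040 and that of proliferation -0.020, and the endothelial, endoplasmic reticulum stress and amacrine and horizontal cell medians lay inside the range. With the mean in place of the median, the cone, visual cycle, melanin, bipolar and amacrine and horizontal cell lists lay inside it.

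The double heterozygote was also set against each homozygote. Against eys-/-, 155 genes were higher and 73 lower among 10448. The largest differences were mhc2daa at 3.71, nr1d4b at 3.41, smu1b at 2.99, tubb4bl at 2.92 and the clock gene per1a at 2.81 on the higher side, and guca1ab.1 at -2.42, kcnk5a at -2.38, ttll6 at -2.26, bmal1a at -2.20 and ndrg1b at -1.71 on the lower side. Against lrp5-/-, 31 genes were higher and 30 lower among 10339, with the smallest robust SD of any pair of arrays (0.17). Here tubb4bl at 2.69, tcnbb at 2.68, the chemokine ccl19a.2 at 2.28, fkbp5 at 2.07 and klf9 at 1.95 were highest, and paqr3b at -2.60, fosb at -2.30, fosab at -1.62, gadd45ba at -1.50 and anxa1b at -1.45 lowest. The values of tubb4bl, mhc2daa and guca1ab.1 are uncertain for the reason given above. The readings of mhc2daa in eys-/- (3.24), bmal1a in the double heterozygote, ccl19a.2 in lrp5-/- and fosb in the double heterozygote lay below the median of their array, so the sizes of these differences are uncertain. Readings of kcnk5a and ttll6 in the double heterozygote and of tcnbb in lrp5-/- lay just above that median, and their sizes are uncertain too.

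Against eys-/-, 5 lists stood apart as higher in the double heterozygote and 6 as lower. The higher ones were circadian clock (median 0.29; of 45, 14 higher and 6 lower), immediate early genes (0.26; of 33, 7 higher and 1 lower), microglia and macrophages (0.44), Muller glia (0.21; 1 of 16 higher) and red blood cells (0.20). The lower ones were heat shock and chaperones (-0.19; 2 of 30 lower), surface epithelium (-0.16; 3 of 41 lower), skeletal muscle (-0.14; of 46, 1 higher and 1 lower), rod phototransduction (-0.12, although 2 of 20 were higher and 0 lower), bipolar cells (-0.10; 1 of 19 higher) and oxidative phosphorylation (-0.08). Against lrp5-/-, 3 lists stood apart as higher and 7 as lower. The higher ones were lymphocytes and antigen presentation (0.24), skeletal muscle (0.10; 1 of 41 higher) and fibrous matrix (0.09; 1 of 39 higher). The lower ones were vitreoretinopathy genes (-0.22), circadian clock (-0.18), glial reactivity (-0.11; 1 of 20 lower), pericytes and smooth muscle (-0.10), surface epithelium (-0.09; 2 of 38 lower), lens (-0.08; 1 of 48 lower) and endoplasmic reticulum stress (-0.07). Where no count is given, 0 genes passed 2-fold. Within the clock genes, the lists by phase made after single values were seen had medians against lrp5-/- of 0.40 for the Per and Rev-erb phase and -0.42 for the Bmal phase.

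Calls shared between genotypes were counted last. The double heterozygote and lrp5-/- shared 25 higher and 12 lower genes, where independent lists of these sizes would share 0.37 and 0.14. The double heterozygote and eys-/- shared 8 higher and 8 lower genes (0.23 and 0.16 for independent lists), and the homozygotes 4 and 6 (0.077 and 0.091). Genes called in both but in opposite directions numbered 2, 1 and 5 in these 3 pairs. Simulated unchanged arrays shared 0 calls, which sets no level for chance, since 0 of 10212 unchanged genes passed 2-fold in simulated data. Across genes, which are not independent replicates, the differences from wildtype correlated at 0.70 between the double heterozygote and lrp5-/-, at 0.31 between it and eys-/- and at 0.28 between the homozygotes, beside 0.51 for simulated unchanged arrays. The covariances were 0.056, 0.024 and 0.018, beside 0.021 in the simulation (range 0.020 to 0.022). Part of any excess may come from the shared array. The covariance of 0.018 between the homozygotes lay below the simulated range. The simulated noise came from pairs of arrays of different genotypes and may be too large, so this does not show that the homozygotes share no changes. Between differences that share no array, the double heterozygote minus eys-/- correlated with lrp5-/- minus wildtype at 0.41 (Spearman 0.33), and the double heterozygote minus lrp5-/- correlated with eys-/- minus wildtype at 0.11 (Spearman 0.08), beside -0.00 in the simulation (range -0.027 to 0.022). The third such pair, the double heterozygote minus wildtype with eys-/- minus lrp5-/-, correlated at -0.29 (Spearman -0.24). Its covariance is fixed by arithmetic from those of the pairs before it, so it is no separate result. The simulated noise was drawn by level and not by sets of genes that vary together between eyes. Its narrow range therefore sets no level for chance for these correlations.

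**Figure D3:**
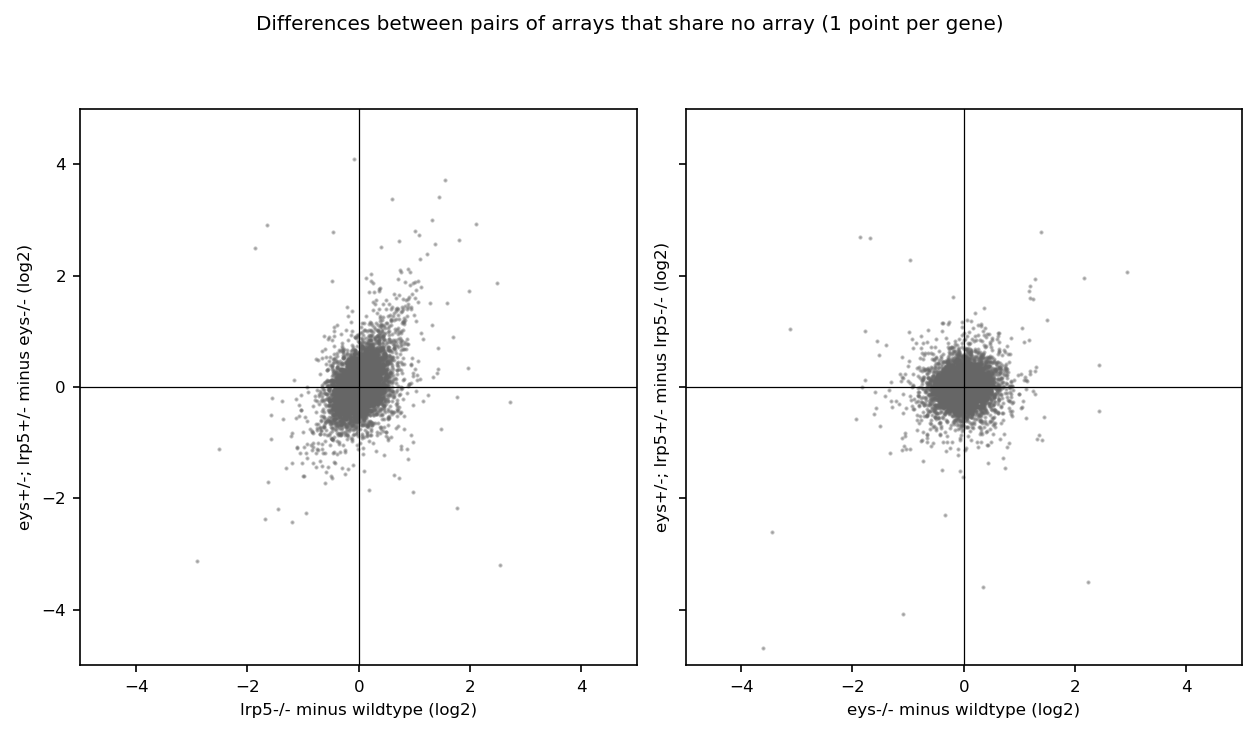
Each point is 1 of 10743 genes, with the log2 difference of a homozygote from wildtype on the horizontal axis and that of the double heterozygote from the other homozygote on the vertical axis. The points of the left panel (lrp5-/- minus wildtype) correlate at 0.41 and those of the right panel (eys-/- minus wildtype) at 0.11.

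Genes on the chromosomes of the mutated genes in assembly GRCz12tu held no excess of calls in the homozygotes. In eys-/-, 1 of 392 measured genes on the chromosome of eys passed 2-fold (0.26%), against 65 of 9844 elsewhere (0.66%). In lrp5-/-, 2 of 307 genes on the chromosome of lrp5 did (0.65%), against 68 of 9916 elsewhere (0.69%). In the double heterozygote the shares were 2.02% on the chromosome of eys and 3.33% on that of lrp5, against 1.71% and 1.67% elsewhere.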

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

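No test in this part was chosen after the result was seen. Probe sets with no gene name were used in no comparison of genes or lists above. Some of them differed from the wildtype array by 2-fold or more. With 1 array per genotype these differences are not shown to be more than noise. Above wildtype were 194 such probe sets in the double heterozygote, 152 in eys-/- and 76 in lrp5-/-. Below wildtype were 140, 114 and 83. Together these are 3.02%, 2.4% and 1.46% of the unnamed probe sets at or above the measured level in each comparison. Of the named genes, 1.72%, 0.63% and 0.67% passed 2-fold. The first shares count probe sets and the second count genes, each by its probe set with the highest mean, so they are not like for like. Their genes were not analysed here.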

How the results depend on the processing

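The counts without clock genes and against the mean of the homozygotes were chosen after the results were seen. The counts of 2-fold genes stayed within 1.5 times of the main value under renormalization, centring, trend removal and either choice of probe set. With no filter on level 161 genes passed in eys-/-, 126 in lrp5-/- and 140 between the double heterozygote and lrp5-/-; under the stricter filter 39 passed in eys-/- and 30 in that last comparison, because other numbers of genes were compared. Against the mean of the other 3 arrays the double heterozygote had 104 (83 higher, 21 lower), lrp5-/- 33, and eys-/- 96 with a split of 34 higher and 62 lower in place of 34 and 32. Against the mean of the 2 homozygotes the double heterozygote had 87 in place of 228 and 61. At 1.5-fold the counts were 643 (double heterozygote), 342 (eys-/-), 340 (lrp5-/-), 797 (double heterozygote minus eys-/-) and 298 (minus lrp5-/-); at 3-fold they were 38, 12, 16, 63 and 17. Without clock genes 162, 64 and 63 genes passed against wildtype in the double heterozygote, eys-/- and lrp5-/-.

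The number of lists standing apart in the double heterozygote went from 11 to 6 against the mean of the other 3 arrays and to 7 with means in place of medians; in eys-/- it went from 16 to 10 under the stricter filter. Counting lists that stood apart before or after, against the mean of the other 3 arrays the sign turned for red blood cells (0.077) and surface epithelium (-0.040) in the double heterozygote for fibrous matrix (-0.0040), proliferation (-0.020) and red blood cells (0.12) in lrp5-/- and for the Bmal phase clock genes in eys-/- (0.34 in place of -0.14, which with no filter was -0.16 and outside the range). The mean turned it for bipolar cells in lrp5-/- (0.0010), and no filter for interferon response in the double heterozygote (-0.23). The mean of the other 3 arrays holds the other mutant arrays, so a shift that they share becomes smaller or can turn sign by construction. For the turns with the mean and with no filter the cause was not tested. Over all lists and settings 1055 values stayed inside or outside the random range as before, 59 no longer stood apart, 31 newly did, and these 8 turned sign; 72 others turned sign without standing apart in either setting, most often against the mean of the other 3 arrays, with means or under another filter. Of the named genes' values 1737 kept their side of 2-fold, 37 fell short of it (32 of them against the mean of the other 3 arrays, among them klf9 in eys-/- at 0.11), 8 passed it and 0 turned sign among those past 2-fold. A further 6 values under 2-fold turned sign, all against the mean of the other 3 arrays, among them lrp5 (0.11) in eys-/- and creg1 (0.028) in the double heterozygote. Of the 1737 values, the 241 with no filter and the 148 under the stricter filter could not change. A filter on level only chooses which genes are compared. Named genes that a setting left out are not counted. A gene with a single probe set also cannot change with the choice of probe set, so the 1737 overstates how much was tested.

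Shared calls at 1.5-fold were 88 (double heterozygote and eys-/-), 204 (double heterozygote and lrp5-/-) and 61 (homozygotes). With no filter they were 31 for the first and 18 for the last pair, and correlations were 0.59 between the double heterozygote and lrp5-/-, and 0.26 and -0.18 for the pairs sharing no array that gave 0.41 and -0.29. Without the clock genes the 0.41 was 0.39, and the double heterozygote and lrp5-/- shared 30 calls in place of 37. Only the listed clock genes were left out, so this does not decide whether time of day shapes the correlation. Without the skeletal muscle, red blood cell, lens and surface epithelium lists the 0.41 stayed at 0.41. Shared calls were then 16 (double heterozygote and eys-/-), 37 (double heterozygote and lrp5-/-) and 9 (homozygotes). No paired analysis was possible because each genotype has 1 array and no test was made. Signals near background carry little information, and this limits the unfiltered values.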

Other observations

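The tests chosen after the result was seen are those of time of day, rods and allele copies for the clock genes, and both tests of the wildtype array; the lists of clock phases, other rod genes, glucocorticoid targets and myelin were also made then. In the double heterozygote 2 rod genes were far above wildtype, the rod transcription factor nr2e3 by 1.91 and pde6ga, a subunit of the rod phosphodiesterase, by 1.67, while the other 18 of the 20 measured genes of the rod list were under 2-fold and the whole list had a median of -0.09. A list of 16 rod genes without nr2e3 and pde6ga, which does not hold every gene of the fixed list, had a median of -0.12. In lrp5-/- nr2e3 and pde6ga differed by 0.99 and 0.71, and in eys-/- by 0.61 and 0.62. Among cone genes of the double heterozygote, the channel subunit cnga3a was higher by 1.07, guca1g and guca1d by 1.14 each, and grk7a differed by 0.85, in contrast to opn1mw1 and guca1ab.1; the guca1 genes are uncertain. These genes were picked after their values were seen.

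Known glucocorticoid targets other than the named genes had medians of 0.28 in the double heterozygote (99.96th percentile), where zbtb16a and zbtb16b were higher by 1.24 and 1.13, and of 0.21 in lrp5-/- (99.98th percentile), but of -0.06 in eys-/- (20.4th percentile; mean -0.17), although fkbp5 was higher by 2.93 there. The 8 measured myelin genes other than mbpa had a median of -0.19 in eys-/- (1.49th percentile), with zwi at -0.83, beside mbpa at -1.59. The genes zbtb16a, zbtb16b and zwi lie outside the naming rule and were picked after their values were seen.

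Clock genes of opposite phase differed from wildtype in opposite directions in lrp5-/- and in the double heterozygote, with medians of 0.44 and 0.84 for the Per and Rev-erb phase and -0.49 and -1.10 for the Bmal phase. Removing a trend with signal level left the gap of the double heterozygote at 1.94, so that trend does not account for it; a larger share of rods would raise rod genes together, but the whole rod list, with its 2 higher genes, had a median of -0.092 (SD 0.61 over genes), against 0.84 for the Per phase. The gap of 1.94 itself is what eyes taken at another time of day than the wildtype eyes would show. This is a candidate explanation. In eys-/- the Per phase median was -0.46 and the Bmal phase median of -0.14 lay inside the random range. Against the mean of the other 3 arrays they were -0.91 and 0.34, and the gap of lrp5-/- was 0.59 in place of 0.92. For eys-/- that reference holds the lrp5-/- and double heterozygote arrays. Their clock shifts enter the -0.91 and 0.34, which are no further evidence about eys-/-. An effect of the alleles that adds up over their copies would put the double heterozygote at the mean of the homozygotes relative to wildtype, but the gap between it and the 2 homozygotes' mean was 1.51, beside at most 1.34 among the other 3 arrays; with 1 array per genotype this cannot be told apart from differences between fish. An effect of the combined genotype on the clock stays open and was not tested.

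The fibrous matrix, surface epithelium and oxidative phosphorylation lists stood apart as higher, and the endothelial and ribosomal protein lists as lower, in all 3 mutant arrays. Once a trend with signal level was removed, 5 of these 5 lists still stood apart in all 3 comparisons. The random lists were matched on level and carry such a trend too, so its removal could change little and is no separate test. A wildtype array that stands apart stays open for each of the 5 lists, and the share of each tissue in the whole eyes was not measured. In 4 of the 4 lists other than ribosomal proteins a median between 2 mutant arrays lay outside the random range, which shows that the mutant arrays also differ from each other but not where the common direction comes from, and in 4 of the 5 lists these medians were smaller than those against wildtype. For the ribosomal protein list the largest median between mutant arrays was 0.034, against -0.14 to -0.17 from wildtype; with 1 wildtype array its own peculiarity cannot be told apart from an effect common to the mutant genotypes, which was not tested.

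Genes next to eys differed more than most windows in the eys-/- array: the 50 nearest measured genes had a median absolute difference of 0.20 against 0.13 over all windows (99.6th percentile), the highest percentile of the 6 windows examined at eys and lrp5. Their signal level does not account for it, as the percentile among random lists matched on level was 99.68, but with 20 and 100 genes it was 97.4 and 94.2, so the pattern depends on the window. If variants linked to the mutant allele were the source, the 1 mutant copy in the double heterozygote could show part of it. Over these genes its difference from lrp5-/- correlated with that of eys-/- from wildtype at 0.24, at the 73.7th percentile of windows, which leaves this open. Set directly against wildtype, the double heterozygote showed no enlargement next to eys. Its 50 nearest measured genes had a median absolute difference of 0.146, against 0.153 over all windows (39.6th percentile). Among the 50 genes in eys-/-, the largest difference with a gene name was that of cpeb3, picked after its value was seen, at 0.71.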
